A study of Mus musculus with 8 samples.

How the data were processed

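RNA from mouse liver was measured on 8 single-colour Agilent arrays of 1 design (Mouse 8x60K format), 4 from mice given a control adenovirus and 4 from mice given an adenovirus carrying a short hairpin RNA against Raly. Group and replicate number were taken from the sample titles. The titles number the samples and do not state that each array is a different mouse, so the p-values measure the spread between these samples. Each array file holds 62976 spots, of which 59305 are not controls and represent 55681 different probes. All 8 arrays lay on 1 slide and were scanned together. The control arrays filled slide row 1 and the shRaly arrays slide row 2, so slide row and group cannot be told apart.

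The intensity values are those of the scanner software, Agilent Feature Extraction version 11.5.1.1 per the file headers. Each deposited array file gives the mean signal intensity of a spot, the median intensity of the local background and a processed signal intensity, which is background-subtracted, corrected for spatial trends, replaced by a surrogate where not above background, and not normalized between arrays, per the file headers. The same deposited files carry flags for spots well above background, non-uniform spots, population outliers and saturation. The deposited table of the whole series was equal to the processed signal for 62976 of 62976 spots on every array, so its scale is linear and it is neither centred nor scaled between arrays. Its columns had medians between 13.3 and 16.4 over the non-control spots. A normalization applied by the authors for their own tests is not given in the sources used here.

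For the present work the processed signal was taken to log2, and each array's 75th percentile over the non-control spots (between 7.86 and 8.19 on the log2 scale) was subtracted. Between 137 and 163 spots per array were flagged as non-uniform or as population outliers and set to missing, and no spot was saturated. Spots of the same probe were averaged. Gene names came from the RefSeq accession in the files through a gene table of assembly GRCm38.p6, which was used for names only. In this way 27656 probes were named by accession, 3401 by a current symbol and 321 by an older symbol, 1774 kept the name in the file, and 22529 had no gene symbol. Coordinates are those of the files, on mouse build mm9 (NCBI37). Exon, intron and UTR annotation on that build was not analysed here.

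A gene was tested if a probe of it was well above background on at least 4 of the 8 arrays and had a value on at least 3 arrays of each group. This kept 19859 probes of 14872 genes. Where several probes of a gene passed, the one with the highest mean over all 8 arrays represented it. Of the 40 genes named under the rule given below, 9 had another probe past the filter, and 2 of these 13 other probes moved in the opposite direction (for Tnfaip6 and Flt1). The groups were compared with limma version 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Where a probe was not well above background on any array of a group, its fold is a bound ("at least"), set from the mean of the brighter group and, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background.

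A set of 35 gene lists (pathways, cell types, liver zones) with 741 members, 733 of them on the array, was fixed before the data were examined. The lists were tested with camera in limma at an inter-gene correlation of 0.01, adjusted over the 35 lists. Beside it stand camera with the correlation estimated from the data and fry, which tests whether a list's genes move, on balance, one way and does not compare the list with other genes. Per-array list values are medians over the list's genes relative to the control mean, and were compared with an exact two-sided permutation test of 4 against 4 arrays, whose smallest p is 0.0286. The genes named were fixed by rule: Raly; Srebf2, Hmgcs1, Sqle, Srebf1 and Abca1 whatever their values; the 8 largest rises and 8 largest falls past the threshold with no overlap of the groups, leaving out clone and predicted-gene names; up to 4 genes past the threshold per list, by smallest p; and, for a list past camera with none, the 2 genes of smallest p as values only. The rule fixed 3 more genes, which stayed in the list tests and counts and are not reported here. Other genes named are said to have been chosen after their values were seen.

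The arrays give no molecule counts, and their number limits the precision. Well above background were between 27228 (shRaly 2, 45.9%) and 30289 (control 4, 51.1%) of the non-control spots. Both tests were tested on simulated data made from the real arrays of shRaly against control, with a known set of changed genes among 14850. At a fold of 1.5, 43.3% of the changed genes were recovered, at a fold of 2, 67.2%, and at a fold of 4, 89.4%, and 6.34% of the calls were false. A simulated shift of the cholesterol list was called by camera with an adjusted p of 2.86e-28, and 0 of the 34 other lists were called. The simulated genes varied independently of each other. In the real data the estimated correlation was 0.38 for the cholesterol list and 0.60 for the type I interferon list. The simulation therefore does not give camera's rate of false list calls on the real arrays. Splits of the real arrays into 4 and 4 other than the real one called 2 to 18 lists.

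The alternatives were normexp background correction with an offset of 50 on the mean and background signals, quantile normalization, scaling to the median, no filter on dim probes, a filter asking for all 8 arrays, the mean of a gene's probes, eBayes with a trend, array weights, outlier spots kept, the replicate number as a block, the deposited table in place of the array files, an estimated inter-gene correlation, and leaving out each array in turn. No pair of arrays held identical values. Figures were drawn with matplotlib 3.10.9.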

Results

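Liver RNA was profiled on day 6 after adenoviral delivery in 12-week-old bl6 mice kept on chow, with 4 control arrays and 4 shRaly arrays. The virus dose in the labels is 2e+09, with no unit given. Raly encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family that has been examined as a partner of a non-coding RNA in the control of cholesterol synthesis genes in liver. The comparison of the groups asks which liver transcripts differ when Raly is knocked down. The arrays were alike in range: 45.9% to 51.1% of spots were well above background, and the correlation over genes was 0.991 to 0.995 among controls, 0.987 to 0.994 among shRaly arrays and 0.987 to 0.993 between groups. The first principal component held 30.2% of the variance and placed all 4 control arrays on one side and all 4 shRaly arrays on the other. On the second component (21.9%) shRaly 1 stood apart, at -41.2.

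Raly signal was lower in the livers that received the hairpin, at 62.5% of the control level on average. Relative to the control mean, the shRaly arrays had 51.8%, 80.9%, 58.3% and 62.7% (replicates 1 to 4) and the control arrays 100.4%, 84.3%, 105% and 112%. The shRaly 2 array was thus close to the lowest control. All 4 shRaly values lay below all 4 control values (exact permutation test, two-sided p = 0.0286, the smallest possible with 4 against 4 arrays). The log2 fold change was -0.68 (SE 0.15, n = 4 and 4), a reduction of 37.5% with a 95% interval of 20.7% to 50.6%. With limma's adjustment over all genes the adjusted p was 0.0748, which does not pass the threshold, and without shRaly 2 it was 0.0297 at a log2 fold change of -0.80. Raly was measured by 1 probe, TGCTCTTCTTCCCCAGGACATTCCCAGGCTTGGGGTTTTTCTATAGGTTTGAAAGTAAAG, at chromosome 2, 154692867 to 154692926 (mm9).

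The genes of cholesterol biosynthesis were lower in shRaly livers as a group. Of the 20 enzymes measured, 11 fell past the threshold, 0 rose, and 9 did not pass; adjusted over the list alone, 17 fell. The list's median log2 fold change was -0.86, or 54.9% of the control level. The largest fall was that of Ebp, the sterol isomerase, to 23.7% of control (log2 -2.07, SE 0.19). Besides Ebp, Mvd, Sqle, Idi1 and Hmgcs1, the genes named here were chosen after their values were seen. Msmo1, the sterol C4-methyl oxidase, fell by 1.31 on the log2 scale (SE 0.17), and Mvd, mevalonate diphosphate decarboxylase, by 1.27 (SE 0.12). Sqle, squalene epoxidase, fell to 47.4% of control (log2 -1.08, SE 0.08), with a limma adjusted p of 0.00178, the smallest in the list. Idi1 (-0.98), Mvk (-0.97), Fdps (-0.95), Dhcr7 (-0.90), Hmgcs1 (-0.80), Cyp51 (-0.77) and Hsd17b7 (-0.63) also fell. Among the 9 others, Lss had a log2 fold change of -1.03 (adjusted p = 0.0542), Nsdhl -0.96 (0.0599) and Pmvk -0.83 (0.0571).

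**Figure D1:**
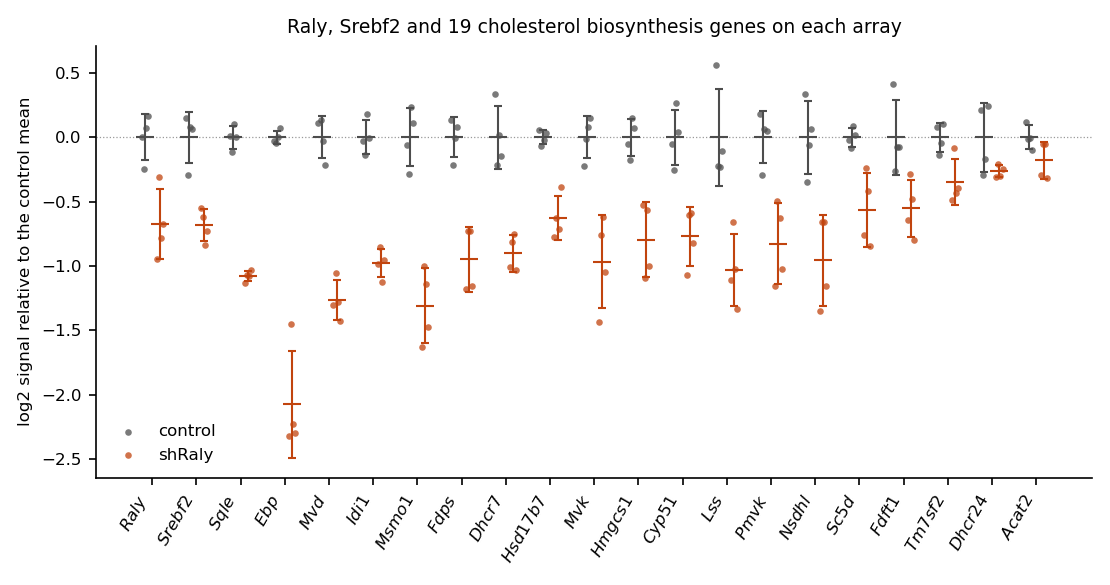
Log2 signal relative to the control mean (vertical axis) for Raly, Srebf2 and 19 cholesterol biosynthesis genes (horizontal axis), with a point per array for control (grey, n = 4) and shRaly (orange, n = 4) and the mean and SD as bars. Ebp lies lowest, with 3 shRaly arrays between -2.32 and -2.23 and shRaly 2 at -1.45.

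On every shRaly array the median of the cholesterol list lay below the controls, at -1.04, -0.66, -0.64 and -1.01 for replicates 1 to 4 (exact permutation test, two-sided p = 0.0286, the smallest possible). With camera the list was lower than the other genes (adjusted p = 9.58e-20; adjusted p = 0.393 with an estimated correlation), and fry gave an adjusted p of 0.0045. The hepatocyte markers measured alongside had a median of -0.06 (18 genes, 0 past the threshold). Leaving out single arrays left the median between -0.95 and -0.80, while the number of members past the threshold ran from 4 (without control 3) to 14 (without shRaly 2).

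Srebf2, the transcription factor that drives cholesterol synthesis and uptake genes, was lower in shRaly livers as well. It fell to 62.3% of control (log2 -0.68, SE 0.12, limma adjusted p = 0.0379), and a second Srebf2 probe had a log2 fold change of -0.26. The Srebf2 call held in 1 of the 8 leave-outs, with adjusted p up to 0.124, and was lost with normexp background correction (-0.42, SE 0.11, adjusted p = 0.0836), with the mean of both probes (-0.47, SE 0.09, 0.0552), with no filter on dim probes (0.110) and with a replicate block (0.115). Its list of other SREBP2 targets and sterol regulators had a median of -0.35 over 11 measured genes, with 1 lower (Srebf2), 0 higher and 10 not past the threshold; adjusted over the list alone, 4 fell. The list passed camera (adjusted p = 0.00635; adjusted p = 0.557 with an estimated correlation) and did not pass fry (adjusted p = 0.0611).

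The other lists of lipid and glucose metabolism did not pass camera, with adjusted p from 0.0918 to 0.756. Fatty acid and triglyceride synthesis had a median of -0.05 over 22 genes with 1 gene past the threshold, Elovl5, a fatty acid elongase of polyunsaturated chains, which fell to 45.1% of control (log2 -1.15, SE 0.12, adjusted p = 0.00981 by limma). Adjusted over the list alone, 3 members fell and 1 rose. Srebf1, which drives fatty acid synthesis genes, had a log2 fold change of 0.11 (adjusted p = 0.857). LXR targets had a median of 0.05 over 12 genes, and Abca1, the cholesterol exporter among them, -0.33 (adjusted p = 0.284). Bile acid synthesis and transport stood at -0.04 (18 genes) and lipoprotein particles at -0.14 (16 genes), with 0 members past the threshold in each. Fatty acid oxidation and ketogenesis had a median of -0.13 over 24 genes. Within it Ppara, the nuclear receptor for fatty acid oxidation genes, fell to 66.6% of control (log2 -0.59, SE 0.11, limma adjusted p = 0.0498). A call this near the threshold held in 1 of 8 leave-outs and in 6 of the 11 other alternatives. The 11 include the deposited table, whose equal values could not change the call. Gluconeogenesis and glycolysis had a median of 0.07 over 17 genes, with 1 higher: Pfkfb3, which makes the glycolytic activator fructose-2,6-bisphosphate, rose 3.68-fold (log2 1.88, SE 0.35).

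Across the array, 182 of 14872 genes passed the threshold, 46 higher and 136 lower in shRaly livers. Of these, 41 higher and 105 lower genes were well above background on all 8 arrays, and among them 12 rose and 20 fell by a factor of at least 2. The steepest rise among named genes was that of Gpx2, a glutathione peroxidase, to 4.69-fold (log2 2.23, SE 0.16, limma adjusted p = 0.00175). The metalloproteinase-family gene Adam32 rose 3.62-fold, Fam13c 2.90-fold and Nrg4, an epidermal growth factor family ligand, 2.85-fold. Colgalt2 rose at least 2.41-fold and Tnfaip6, an inflammation-induced hyaluronan-binding protein, at least 1.61-fold, since neither was well above background on any control array. A second Tnfaip6 probe, brighter on the control arrays, had a log2 fold change of -0.06, and with the mean of its probes Tnfaip6 lost the call (0.76, SE 0.24, adjusted p = 0.171). Rundc3b also passed the threshold as higher; it was well above background on 3 of the 4 control arrays, so no fold is given. The 8 falls named by the same rule were in genes with faint signals. Mcpt9, a mast cell protease, fell at least 3.70-fold, the transcription factor gene Tfap2c at least 2.61-fold and Ifnb1, interferon beta, at least 2.52-fold. Nebl fell at least 1.77-fold, Stmn2 and the intestinal alkaline phosphatase gene Alpi at least 1.51-fold each and the olfactory receptor gene Olfr1233 at least 1.44-fold, all with no shRaly array well above background. Efcab10 also passed the threshold as lower; it was well above background on 1 shRaly array, so no fold is given. These bounds are on the scale of the scanner's processed signal. With normexp background correction, which adds 50 to every signal, all 8 falls lost the call and were smaller than their bounds where one is given: Mcpt9 went from -2.60 (SE 0.22) to -0.60 (SE 0.16, adjusted p = 0.0777), Tfap2c from -2.62 (SE 0.49) to -0.47 (SE 0.17, 0.213) and Ifnb1 from -2.23 (SE 0.38) to -0.41 (SE 0.15, 0.208), and the other 5 stood between -0.52 and -0.10.

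**Figure D2:**
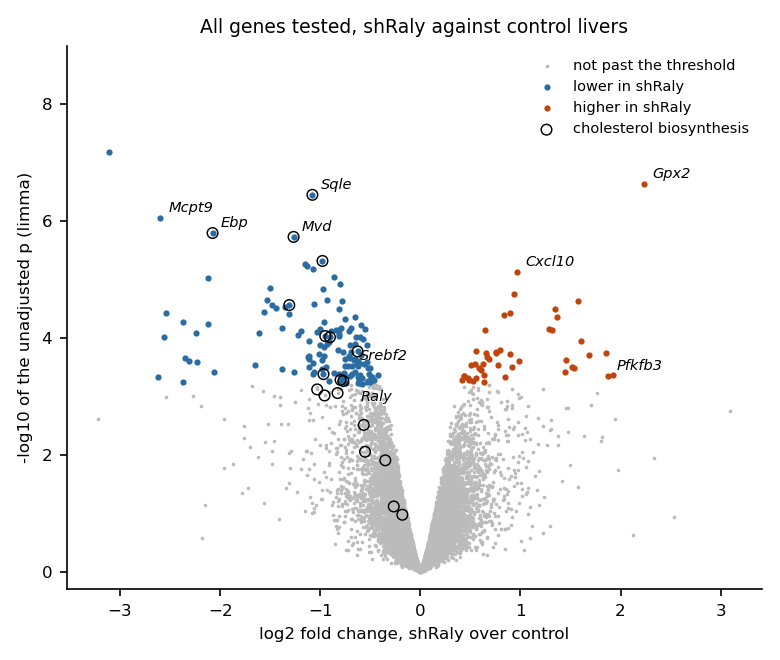
Log2 fold change of shRaly over control (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 14872 genes, with the 136 lower genes in blue, the 46 higher genes in orange, the others in grey, and 19 cholesterol biosynthesis genes circled. Sqle, Ebp and Mvd are near the top on the left, and Gpx2 is farthest up on the right.

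The number of genes past the threshold depended on single arrays. It was 55, 17, 21 and 49 without control 1, 2, 3 and 4, and 119, 285, 47 and 20 without shRaly 1, 2, 3 and 4. Of the 25 named genes past the threshold, 8 stayed past it in all 8 leave-outs: Sqle, Ebp, Mvd, Idi1, Elovl5, Gpx2, Cxcl10 and Mcpt9. Of these, Mcpt9 lost the call with normexp, as given above, and Idi1 with a replicate block (adjusted p = 0.0559). With normexp 11 of the named calls were lost: the 8 falls, Srebf2, Tnfaip6 (0.45) and Fam13c (0.71). Among the rises that kept the call with normexp, the log2 fold change was 1.14 for Gpx2 and 0.57 for Colgalt2. With no filter on dim probes 15 of the named calls were lost, and with a replicate block 11. At an unadjusted p under 0.05 there were 2397 genes, and the groups did not overlap for 1545 genes (10.4%, against 2.86% expected by chance on average). How far that share varies between splits of the arrays was not computed, so the excess is not tested.

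Outside lipid and glucose metabolism, 5 lists had higher values in shRaly livers by camera, none with an estimated correlation. Cell cycle and proliferation had a median of 0.39 over 29 genes, 0 past the threshold (adjusted p = 1.50e-06; adjusted p = 0.881 with an estimated correlation). Its array medians were 0.38, -0.06, 0.95 and 0.45 for shRaly 1 to 4, so shRaly 2 lay among the controls (exact permutation test, two-sided p = 0.114), and the median without shRaly 3 was 0.23. Aurka and Plk1, mitotic kinases, had log2 fold changes of 0.83 (adjusted p = 0.173) and 0.74 (0.116). The type I interferon list had a median of 0.25 over 30 genes, 0 past the threshold (adjusted p = 1.93e-06; adjusted p = 0.881 with an estimated correlation), with 0.13, 0.02, 0.51 and 0.48 on shRaly 1 to 4. Rsad2 and Ifit1, antiviral effectors of that list, stood at 0.97 (adjusted p = 0.117) and 0.78 (0.126). In the interferon gamma and antigen presentation list (median 0.11, 23 genes, adjusted p = 0.0146; adjusted p = 0.881 with an estimated correlation), the chemokine Cxcl10 rose 1.95-fold (log2 0.97, SE 0.10, limma adjusted p = 0.0103). Adjusted over the list alone, 3 of its members rose and 1 fell.

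The inflammatory cytokine list had a median of 0.24 over 16 genes, 0 past the threshold (adjusted p = 0.0478; adjusted p = 0.881 with an estimated correlation). Its leading members went opposite ways, Tnfaip3, an inhibitor of NF-kB signalling, at 0.86 (adjusted p = 0.0763) and the cytokine Il1b at -0.78 (0.0505); adjusted over the list alone, 4 members rose and 1 fell. NRF2 targets, genes of the oxidant response, had a median of 0.10 over 17 genes, 0 past the threshold and 3 higher adjusted over the list alone (adjusted p = 0.0184; adjusted p = 0.557 with an estimated correlation). Nqo1, the quinone reductase, stood at 0.93 (adjusted p = 0.105) and Gstm1, a glutathione transferase, at 0.31 (0.121). The Gstm1 probe used has coordinates on chromosome 5, and another Gstm1 probe, at 0.41, on chromosome 3. Lower by camera were complement and coagulation (median -0.11, 32 genes, 0 past the threshold, adjusted p = 0.0321; adjusted p = 0.881 with an estimated correlation) and endothelial markers (median -0.16, 19 genes, 0 past the threshold, adjusted p = 0.0478; adjusted p = 0.557 with an estimated correlation). Masp2 and Cfi, of the complement system, stood at -0.45 (adjusted p = 0.0599) and -0.38 (0.188), and the endothelial genes Stab2 at -0.31 (0.157) and Flt1 at -0.38 (0.21). Other Masp2 probes had -0.52 and -1.23, and with the mean of its probes Masp2 passed the threshold (-0.74, SE 0.10, adjusted p = 0.0181). A second Flt1 probe had the opposite sign, 0.16. By fry 1 of the 35 lists passed, the cholesterol list, and the lists that passed camera outside lipid metabolism had fry adjusted p from 0.0929 to 0.382. Over the 8 leave-outs the camera call held in 2 for endothelial markers, 3 each for complement and coagulation and for inflammatory cytokines, 6 for interferon gamma and antigen presentation and 7 for NRF2 targets.

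**Figure D3:**
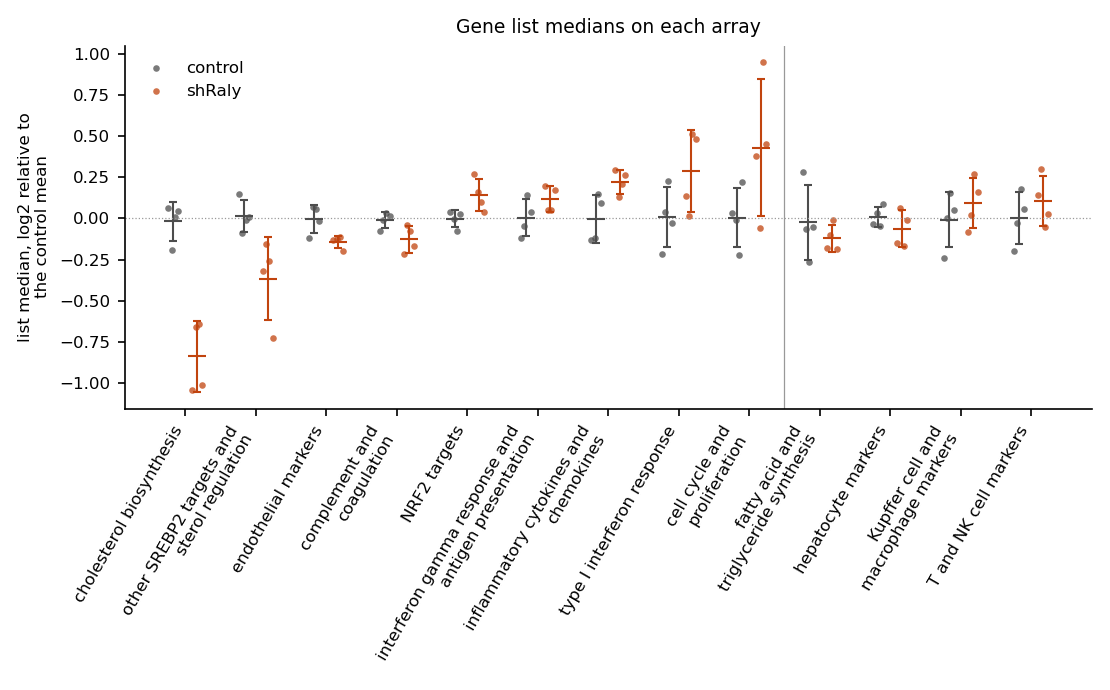
Median over each list's genes of log2 signal relative to the control mean (vertical axis) for 13 gene lists (horizontal axis), with a point per array for control (grey, n = 4) and shRaly (orange, n = 4) and the mean and SD of the array medians as bars. The 9 lists left of the line passed camera; the cholesterol list is the lowest, with shRaly arrays between -1.04 and -0.64, and in the cell cycle list the shRaly arrays spread from -0.06 to 0.95.

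Markers of the liver's cell types gave no list past camera apart from the endothelial one, with adjusted p from 0.269 upwards. Hepatocyte markers had a median log2 fold change of -0.06, Kupffer cell and macrophage markers 0.03, T and NK cell markers 0.12, B and plasma cell markers -0.18, neutrophil markers 0.27, dendritic cell markers 0.09, stellate cell and fibroblast genes -0.12 and cholangiocyte markers -0.12, with 0 members past the threshold in each. Adjusted over the list alone, 3 T and NK cell markers rose and 3 fell. Pericentral and periportal hepatocyte genes stood at -0.00 and 0.04, red blood cell markers at -0.05 and markers of adjacent tissues at -0.09. The remaining lists also had 0 members past the threshold and did not pass camera: acute phase response (-0.11), p53 targets (0.12), unfolded protein and integrated stress response (0.01), xenobiotic cytochromes P450 (-0.15), circadian clock genes (0.03), sex-biased genes (-0.05), hnRNP and splicing factors (-0.01) and the mitochondrial respiratory chain (0.02).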

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

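The tests in this part were chosen after the results were seen, except the counts over other splits of the arrays for the gene lists and for the probes with no gene symbol.

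The cholesterol biosynthesis list was lower in shRaly livers, with a median log2 fold change of -0.86. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave a median of that size, the real one. The highest of the others was 0.60. Chance assignment of the arrays is thus argued against at the 0.05 level and not excluded, since 1 of 35 is the smallest share the splits allow. The tables argue against a lower share of hepatocytes, whose markers had a median of -0.059 and, set against the cholesterol list array by array, separated the groups (exact permutation test, two-sided p = 0.0286), and against a shift of whole-array scaling, since the list median minus the median of all genes on the same array, from which a scaling factor of the array cancels, differed between the groups by -0.81 (exact permutation test, two-sided p = 0.0286), and the list had medians of -0.85 and -0.89 under quantile and median scaling. Both p-values equal that of the cholesterol list alone, whose array medians already separated the groups, so they add no evidence of their own. The weighing rests on the sizes, -0.059 and -0.81. The position of the groups on the slide cannot be told apart from the knockdown, because 0 slide rows held both groups. The effect of the hairpin on Raly, or an effect of the hairpin on other transcripts, may account for the fall and stays open as a hypothesis.

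A group of 82 probes was well above background on all 4 control arrays and on no shRaly array, against 8 probes the other way round. The count of 8 asks for detection on shRaly 2, which had 45.9% of spots well above background. The other arrays had 49.1% to 51.1%, so the imbalance of the 2 counts may come partly from that array. The 82 probes include Mcpt9, Tfap2c and Ifnb1. Of the 35 splits of the arrays 1 gave as many, the real one, with 56 as the highest of the others. That is the smallest share the splits allow. The pattern was picked after the results were seen, so chance is argued against and not excluded. One short sequence shared by the probes is argued against, since the commonest 8-base word occurred in 4 of them, as many as in 36.8% of 1000 random sets of comparable probes. For uneven background over the array surface, dim spots next to the probes were compared. The probes differed by -0.67 (log2 mean signal, shRaly minus control, SD 0.29), and dim spots next to them by -0.093 (SE 0.0089). All dim spots had a median difference of -0.041. The probes were picked for their difference and the neighbours were not, so the neighbours were bound to differ less. A local shift as large as that of the probes was not seen, and a smaller one is not excluded. The position of the groups on the slide could produce the difference of the probes and cannot be told apart from the virus, as 0 slide rows held both groups. Transcripts of low level in the livers or sequences carried by the control virus were not tested.

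The cell cycle list had a median of 0.39, and 4 of the 35 splits gave a median of that size (highest other 0.57), so chance could account for it. The shRaly 3 array was not alone above the controls. The shRaly 1 and shRaly 4 arrays stood at 0.38 and 0.45, above the highest control (0.22), while shRaly 2 lay among the controls. Without shRaly 3 the exact permutation p of the array scores was 0.2 (two-sided), so a difference without that array is not established. The mean of the Kupffer and T and NK cell scores rose by 0.10, against 0.43 for the cell cycle score. The cell cycle score minus that mean gave an exact permutation p of 0.286 (two-sided), so more immune cells are not excluded. The type I interferon median of 0.25 was reached by 7 of the 35 splits (highest other 0.40).

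The count of 182 genes past the threshold was reached by 1 of the 35 splits, the real one, with 0 genes as the highest of the others. That is the smallest share the splits allow, and the test was chosen after the results were seen. For that count chance is argued against and not excluded. The count of 9 gene lists past camera was reached by 10 of the 35 splits, with up to 18 lists, so chance is not excluded for the number of lists. Every other split called lists as well, from 2 to 18. Among probes with no gene symbol 41 of 7075 passed the threshold, 5 of them higher in shRaly and 36 lower. These overlap with the faint probes above, 45 of which have no gene symbol: 20 of the 36 were well above background on no shRaly array. For the count of 41, 1 of the 35 splits gave as many, and the highest of the others was 27.

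In 9 of 152 sets of 4 arrays examined, 1 array lay far from the other 3, where chance alone gives about 7.6. The shRaly 2 array had 45.9% of spots well above background, against 50.3% to 51.1% on the other shRaly arrays. On the same array Ebp stood at -1.45 relative to the control mean (others -2.32 to -2.23) and the p53 target list at -0.12 (others 0.21 to 0.23). The shRaly 1 array stood apart in bile acid synthesis and transport (-0.18), acute phase response (-0.23) and periportal hepatocyte genes (-0.18). The shRaly 3 array had the red blood cell list at 0.49. Among controls, replicate 3 had Il1b at 0.25 and cholangiocyte markers at 0.42.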

How the results depend on the processing

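The count of 182 genes was 42 (9 higher, 33 lower) with no filter on dim probes, where 24028 genes were tested, and 492 (143 higher, 349 lower) with array weights; the cause of the latter was not tested. With a replicate block it was 46 (11 higher, 35 lower), of which 36 were among the 182. Same-numbered arrays lay in the same slide column. The correlations of their deviations were 0.09, -0.02, -0.07 and 0.14, and not every array correlated best with its own number. These values do not show a pairing of the samples by number, and so few arrays cannot exclude one. Leaving out single arrays gave 17 (without control 2) to 285 (without shRaly 2) genes. The other alternatives kept the count within 1.5 times, from 133 (scaling to the median, 82.7% lower against 74.7%) to 269 (eBayes with a trend); with normexp it was 253, of which 115 were among the 182. The deposited table holds the same values and so could change nothing. Raly kept its direction throughout and passed the threshold with normexp (-0.71, adjusted p = 0.0111), with a trend (-0.68, 0.0417) and without shRaly 2 (-0.80, 0.0297), the cause not tested; leave-outs gave -0.80 to -0.59 and the adjusted p over all alternatives ran up to 0.193. The cholesterol list passed camera in every alternative with a preset correlation (median -0.95 to -0.80) and lost the call with an estimated correlation (-0.86, p = 0.393), as did every list (9 to 0). Leave-outs gave 4 (without shRaly 1) to 9 lists. The cholesterol, SREBP2, cell cycle and type I interferon lists passed in all 8 leave-outs and all 11 other alternatives at the preset correlation. Of those 11, endothelial markers passed in 5, inflammatory cytokines in 6 and complement and coagulation in 8. Interferon gamma and NRF2 targets passed in 10 each, both lost with normexp. The 11 include the deposited table, which holds the same values, and eBayes with a trend, which camera does not use. Neither could change a camera call. Lists outside the 9 also passed under some alternatives. With normexp 3 lists were higher and 6 lower. With no filter on dim probes 4 were higher and 6 lower, against 5 and 4 in the main fit. Without shRaly 2, 6 lists were higher. Of 730 values of 39 named genes under the alternatives, 565 kept direction and side of the threshold, 146 lost the call, 18 gained it and 1 changed sign: Srebf1 without shRaly 2 (-0.016, against values up to 0.33 under the others), the cause not tested. The deposited table gave 39 of the 565, which its equal values fixed in advance. Of the 146 losses, 100 came with replicates left out, with up to 16 without control 3 and 16 without shRaly 4. Among the other alternatives, calls were lost most with no filter on dim probes (15), with normexp (11) and with a replicate block (11). They were also lost with quantile normalization (Rundc3b, Hmgcs1, Ppara), the mean of a gene's probes (Tnfaip6, Srebf2, Ppara), scaling to the median (Pfkfb3, Hmgcs1) and outlier spots kept (Ppara). Apart from leave-outs, calls were gained by Il1b in 5 alternatives, Masp2 in 4, Tnfaip3 in 2, and Nqo1 and Flt1 in 1 each, with array weights. Signal over background limits the genes whose shRaly probes were not well above background, 18 of the 182, and several of these have no value under the filter asking for all 8 arrays.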

Other observations

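The genes named in this part were chosen after their values were seen.

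Several genes outside the fixed lists passed the threshold in the shRaly livers. Lower were Lipa, the lysosomal acid lipase that frees cholesterol from lipoprotein esters (log2 -1.44, SE 0.19), and the water channel gene Aqp8 (-1.11, SE 0.17). Also lower were F3, coagulation tissue factor (-1.11, SE 0.19), and Atf6, a membrane-bound sensor of endoplasmic reticulum stress (-1.06, SE 0.13). Ddost, a subunit of the oligosaccharyltransferase, stood at -0.80 (SE 0.11), Igf2r, the mannose 6-phosphate receptor, at -0.52 (SE 0.09), and Erg28, an endoplasmic reticulum protein linked to sterol synthesis, at -0.48 (SE 0.09). Higher were Lrp2, the endocytic receptor megalin (1.45, SE 0.26), the nicotinic acid receptor gene Hcar2 (1.32, SE 0.19), Mthfd1l, of mitochondrial folate metabolism (0.98, SE 0.17), the kinase gene Sik1 (0.90, SE 0.15) and the transporter gene Abcb1b (0.83, SE 0.11). The limma adjusted p of these 12 genes lay below 0.05 in the fit of all 14872 genes. All 12 stayed past the threshold with normexp background correction, where Hcar2 stood at 0.64 and Abcb1b at 0.42. With no filter on dim probes 10 lost the call (all but Lipa and Atf6), with a replicate block 10 (all but Lipa and Hcar2), with median scaling Igf2r, Erg28 and Lrp2, and with the mean of a gene's probes Aqp8. The calls depended on single arrays: over the 8 leave-outs Atf6 held in 6, Lipa in 5, Hcar2 and Abcb1b in 4, Aqp8 and Ddost in 3, Lrp2 in 2, and F3, Igf2r, Erg28, Mthfd1l and Sik1 in 1 each.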
